A study of Mus musculus with 10 samples.

How the data were processed

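Kidney RNA of 10 mice was sequenced as polyadenylated RNA in single-end reads, per the labels' protocols. Per the submitters' processing notes, the tools STAR, featureCounts and edgeR and the genome build mm10 (GRCm38) are named. Per the file headers, featureCounts 1.5.2 counted primary alignments over exons, summed by gene, with the UCSC mm10 gene annotation. A read that overlapped several genes was given to each of them, and no strand option was set, so overlapping and antisense genes share reads. The authors deposited 1 table of raw counts per library, a matrix that joins them, and a table of normalized log2 values. The joined matrix equalled the single tables in all 10 columns. The deposited log2 values of 13645 genes equalled log2 CPM with TMM scaling as voom computes it, to within 4.97e-14. The filter that chose those genes is not given in the sources used here.

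Groups came from the labels: 4 KO and 4 WT animals of C57BL/6N, and single WT animals of 129S2_SvPasCrl and DBA_2J. The series' design text gives 4 male animals per genotype. The replicate numbers follow accession order and pair nothing. No 2 replicates agreed within sampling noise (chi-square per degree of freedom of 11.05 or more for every pair of the 8 libraries). Sample titles with and without a leading E held 2 KO and 2 WT animals each. The labels do not say whether the forms mark a batch, so the form was not in the main model and was tried as a term. The first number in a title was never shared by KO and WT animals. What it marks is not in the labels, so an effect of it cannot be told apart from genotype. The first principal component of log2 CPM (34.4% of variance) parted KO (−25.2 to −18.5) from WT (19.5 to 26.2).

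Counts of the 8 C57BL/6N libraries were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM scaling and the quasi-likelihood F test (glmQLFit, glmQLFTest) on genotype alone. P-values were adjusted by Benjamini-Hochberg over 15547 genes, with calls at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Deposited raw counts were turned into CPM (counts per M of the library total, scaled) with the same factors for means and SDs. CPM of the strain libraries used TMM scaling over all 10 libraries, and so did the WT means set beside them in the comparison of strains; elsewhere WT means come from the scaling of the 8 libraries, which gives slightly different values. The biological coefficient of variation was 12.3%. Depth ran from 19.79 to 57.25 M counts, so a gene at 1 CPM has about 19.79 counts in the shallowest library. Depth differs with genotype, so the calls were repeated after thinning every library to the smallest total, a step chosen after the data were seen.

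Gene lists (47, with 687 symbols) were written before the data were examined, as were the models, most alternatives and the naming rule. Of the symbols, 669 matched the tables directly, 2 by an older symbol and 16 not at all. Genes encoded in mitochondria were not analysed here. Lists with 4 or more tested members (42, without a list of sex-linked genes that checked the labels) were tested with camera at a preset correlation of 0.01 and, as an alternative, an estimated one, and with fry in limma 3.58.1. The neutrophil, adrenal and skeletal muscle lists had too few tested members (3, 1 and 1), with medians of −0.39, −0.29 and −0.29. In the check of the labels as male, Ddx3y, Kdm5d and Eif2s3y were read in every library and did not pass the test, while Uty was called higher in KO (log2 fold change 0.34), a call kept only without KO replicate 1 among fits with 1 library left out (adjusted p = 0.0566 to 0.104 in edgeR in the others). S100a9, Star and Mylpf, of the short lists, did not pass.

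Named genes are Ehhadh; the 12 largest rises and 12 largest falls among called genes with 1 CPM or more in the higher group and no overlap of the groups; up to 4 called members of each list by smallest p, or up to 2 where none was called; up to 6 called genes near Ehhadh; and 6 genes per direction for each strain library. Other genes are named where a count of 5 or fewer needed it or the text says that they were chosen after their values were seen; some members named with a list (such as Itgb6, Shmt2, Mcm2, Mcm3, Nqo1, Hsd17b4, Cyp51 and Ebp) are of this kind. Some genes that the rule picks are not reported here. Exons of some named genes overlap those of another gene, so their counts are uncertain: Acsm3 with Eri2 (743 shared bases), Nphs1 with Nphs1os (597), Cxcl16 with Zmynd15 (363), Pfkp with Pitrm1 (276), Acox3 with 4931431C16Rik (240), Slc7a7 with Oxa1l (228), Tagln with Pcsk7 (95) and Atf5 with Nup62-il4i1 (82). The share of called genes within 20 Mb of Ehhadh was compared with the rest by a two-sided Fisher's exact test, with Ehhadh left out. Strain libraries have no replicate, so log2 CPM (prior count 2) was compared by size alone, and list medians were placed among 10000 random lists of the same size and expression. Agreement across genes was set against 100 simulations of unchanged groups with the same library sizes and dispersions.

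The tests were tested on simulated data first. In 5 simulations of the KO against WT comparison over 15547 genes, 200 genes each were changed by a set fold. Of these edgeR recovered 54.9% of genes changed 1.5-fold, 81.8% of those changed 2-fold and 94.8% of those changed 4-fold. Of all its calls 5.6% were false. The lists named next were shifted in the same simulations, and calls of their genes counted as true. Camera called 20 of 20 lists of 20 genes shifted by 0.5 on the log2 scale and 0 of 180 unshifted lists; the simulated genes were independent of each other, unlike real ones. Alternatives were DESeq2 1.42.0, limma-voom, limma on the deposited log2 values, RLE scaling, no filter, all 10 libraries, the title form as a term or as a subset, other thresholds and windows, and each replicate left out in turn. Figures were drawn with matplotlib 3.10.9.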

Results

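RNA was measured in kidneys of adult male mice that carried or lacked a working Ehhadh gene. Ehhadh encodes the peroxisomal L-bifunctional enzyme, which catalyses the hydratase and dehydrogenase steps of peroxisomal fatty acid β-oxidation. The series held 10 polyadenylated RNA libraries, each from 1 animal: 4 Ehhadh knockout (KO) and 4 wild-type (WT) animals of the C57BL/6N strain, and 1 WT animal each of the strains DBA_2J and 129S2_SvPasCrl. The 4 WT libraries of C57BL/6N are called WT below, and the other strains by name. Total gene counts ran from 19.79 to 57.25 M (mega) per library. KO libraries were deeper than WT libraries, at 47.2 ± 4.8 M against 29.8 ± 7.0 M (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allow). Of 24062 genes in the tables, 15547 passed the expression filter.

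The first question was whether the genotype labels matched the libraries. Ehhadh (chromosome 16, 21761285 to 21787834, minus strand, mm10; 7 exon entries) was read at 260 ± 65.5 CPM in KO and 2492 ± 634 CPM in WT (SD, n = 4 each). This was a 9.58-fold lower level (log2 fold change −3.26, SE 0.21; edgeR quasi-likelihood test, adjusted p = 1.86e-05). The KO libraries read 285, 331, 248 and 176 CPM and the WT libraries 3439, 2232, 2100 and 2197 CPM, so every library lay on the side its label gives. Transcript from the locus was still counted in KO at 260 CPM, and gene totals do not show which exons it came from. The 129S2_SvPasCrl library read 788 CPM and the DBA_2J library 796 CPM, both under the lowest WT library. Titles of the samples came in 2 forms, with and without a leading E, and each form held 2 KO and 2 WT animals. The Ehhadh difference was −3.36 in the first and −3.17 in the second.

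The main comparison asked which kidney transcripts change when Ehhadh is lost. Many tubular injury, cell cycle and lysosomal genes rose in KO, and many genes of the collecting duct and distal tubule and some of peroxisomal β-oxidation fell. Among the largest rises were Havcr1, which encodes the tubular injury protein KIM-1 (1.81 ± 0.566 CPM in WT, 44.9 ± 20.8 in KO, 24.2-fold), and Sox9, a transcription factor of injured and regenerating tubule cells (0.606 ± 0.203 to 11.7 ± 4.23 CPM, 18.8-fold). Cyp27b1, which makes active vitamin D in the proximal tubule, rose 10.2-fold to 92.1 ± 29.4 CPM. Hpd, an enzyme of tyrosine breakdown, was 9.41-fold lower (111 ± 40.9 CPM in WT, 11.8 ± 2.43 in KO), and Dnase1, a secreted nuclease, 3.53-fold lower (1555 ± 175 against 441 ± 103 CPM). With the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, 1710 genes were called, 982 higher and 728 lower in KO.

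Of the called genes, 242 differed by a log2 fold change of 1 or more in size, 187 of them higher and 55 lower. The KO and WT libraries did not overlap in 2755 of the 15547 tested genes (17.7%, against 2.86% by chance), and in 1593 of the 1710 called genes. Further genes among the 12 largest rises encode proteins of muscle and of the cytoskeleton, Xirp2 (log2 fold change 6.22, SE 0.54; 2.73 ± 0.831 CPM in KO), Flnc (3.24, SE 0.20) and the small heat shock protein gene Hspb8 (3.05, SE 0.19; 7.10 ± 2.17 to 59.6 ± 8.5 CPM), with Popdc3 (4.39, SE 0.30) and Areg, which encodes the growth factor amphiregulin (3.90, SE 0.70). The folds of Xirp2 and Areg rest on WT levels near 0 (means of 0.0308 and 0.1 CPM) and are uncertain in size. In animals with and without a leading E in their titles the log2 differences were 4.90 and 5.43 for Xirp2 and 2.36 and 4.69 for Areg. The remaining rises, Rbmy, Gm3376, Gm21693 and Gm21708, are entries of a multicopy family on the Y chromosome whose exons overlap in the annotation, so their counts share reads and are not 4 separate results. Their KO means ran from 1.36 CPM for Gm3376 to 2.49 CPM for Rbmy, and their WT means from 0.0683 to 0.225 CPM. The other large falls were Hrg (−2.22, SE 0.44), Tmprss9 (−2.04, SE 0.21), Azgp1 (−1.92, SE 0.25), Nxpe3 (−1.79, SE 0.23), Ccno (−1.74, SE 0.33), Anks1b (−1.67, SE 0.39), Ctnna2 (−1.65, SE 0.32), Col19a1 (−1.61, SE 0.43), Gm21057 (−1.60, SE 0.31) and Srd5a2, which encodes a steroid 5α-reductase (−1.57, SE 0.33). The adjusted p of these falls in edgeR ran up to 0.0357 for Col19a1. Ccno, Ctnna2, Gm21057 and Anks1b were low in both groups, so the sizes of their falls are uncertain. Their means were 1.31, 1.26, 1.42 and 2.09 CPM in WT and 0.384, 0.398, 0.467 and 0.654 CPM in KO. The call of Anks1b was lost without KO replicate 1 or WT replicate 2 (adjusted p = 0.0616 in edgeR for each), and that of Col19a1 without KO replicates 2 or 4 or WT replicates 2, 3 or 4 (0.0575 to 0.0913).

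A test of title form by genotype called 0 genes in edgeR (1035 at an unadjusted p under 0.05; no other tool was run for it). Animals with a leading E alone (2 against 2) gave 92 higher and 51 lower genes, those without it 924 and 799. Leaving out KO replicate 1 gave 610 higher and 395 lower genes, and leaving out WT replicate 3 gave 625 and 381. Without KO replicate 2 the lower genes numbered 407, and without WT replicate 1 they numbered 465.

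**Figure D1:**
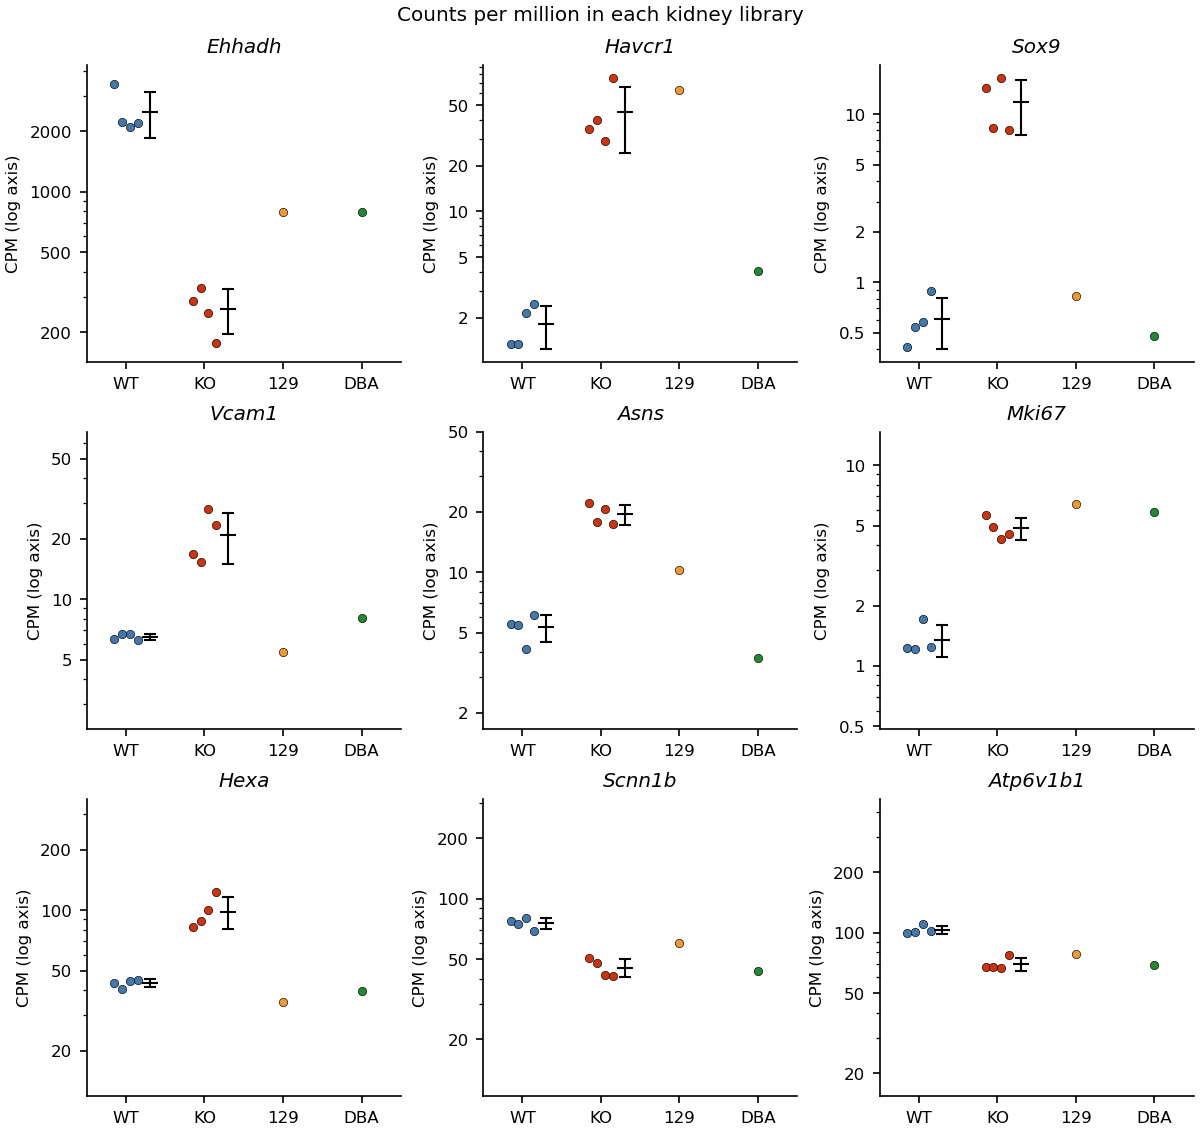
CPM (log axis) of 9 genes in each library of WT, KO, 129S2_SvPasCrl (129) and DBA_2J (DBA); dots are animals, bars the mean ± SD of the 4 WT or 4 KO animals. Ehhadh, Scnn1b and Atp6v1b1 lie lower in all 4 KO libraries than in all WT libraries, the other 6 genes higher.

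Gene lists for pathways, nephron segments and other cell types were compared next. Of 29 tested tubular injury genes 19 rose, 1 fell and 9 did not pass (adjusted over the list alone, 21 rose and 2 fell), with a median log2 fold change of 0.95. Vcam1, an adhesion molecule of injured tubule cells, rose to 20.9 ± 5.93 CPM in KO (log2 fold change 1.68, SE 0.18) and Anxa3 from 12.2 ± 0.879 to 29.5 ± 6.29 CPM. The member that fell was Itgb6 (−0.41, SE 0.12), whose call was lost in edgeR without any 1 library but WT replicate 4 (adjusted p = 0.0634 to 0.127). Cell cycle genes rose in 10 of 22 members with none lower (12 adjusted over the list alone; median 0.99). They included the proliferation marker Mki67 (1.35 ± 0.245 to 4.85 ± 0.594 CPM), the mitotic kinase gene Cdk1 (log2 fold change 2.25, SE 0.34), Ccnb2 (1.63, SE 0.29) and Cdc20 (1.10, SE 0.19). The replication helicase genes Mcm2 to Mcm6 did not pass, with log2 fold changes from −0.02 for Mcm3 to 0.16 for Mcm2.

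Camera with a preset correlation of 0.01 on the edgeR fit called 24 of 42 lists, 9 upward and 15 downward, and 5 of them were called with an estimated correlation. Those 5 were tubular injury (adjusted p = 0.000875 with an estimated correlation), principal cell (0.00731), intercalated cell (0.0175), cell cycle (0.0211) and lysosome (0.0382). With the preset correlation, 5 of the 35 splits of the 8 libraries into 4 and 4 called 24 or more lists. These include the genotype split, and the others hold 3 of the 4 KO libraries on the same side. They thus keep part of the genotype difference and are no measure of chance. Splits with 2 KO libraries on each side called 3 to 16 lists. A list called only with the preset correlation carries less weight than a list called both ways. Fry called 22 lists with a direction. Of all 15547 tested genes, 982 were called higher and 728 lower. A count of members near these shares is no result about its list.

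Lysosomal genes and lists of stress responses were examined next. Of 21 lysosome and autophagy genes, 12 rose and none fell (15 and 1 adjusted over the list alone). They included Hexa, a β-hexosaminidase subunit (43.3 ± 1.93 to 98.4 ± 17.8 CPM), the cathepsin genes Ctsl (479 ± 34.6 to 714 ± 13.1 CPM) and Ctsz (170 ± 5.23 to 235 ± 13.7 CPM), and Lamp1 (log2 fold change 0.47, SE 0.06). Of 19 genes of the ATF4 amino acid stress response, 9 rose and Shmt2 fell (the same counts adjusted over the list alone). The call of Shmt2 was lost in edgeR without KO replicate 1 (adjusted p = 0.0665), KO replicate 2 (0.055), WT replicate 3 (0.0648) or WT replicate 4 (0.051). Asns, asparagine synthetase, went from 5.31 ± 0.822 to 19.5 ± 2.19 CPM, with Mthfd2 (1.58, SE 0.16), Atf5 (1.06, SE 0.12) and Phgdh (1.01, SE 0.11). The median of this list was 0.78 and its camera call was lost with an estimated correlation (adjusted p = 0.0583). p53 target genes rose in 5 of 12 members (7 adjusted over the list alone; adjusted p = 0.0671 with an estimated correlation), led by Eda2r (1.70, SE 0.33) and Bbc3 (0.74, SE 0.17; adjusted p = 0.0545 in edgeR without KO replicate 1). NRF2 targets of oxidative stress rose in 4 of 20 members (9 adjusted over the list alone; adjusted p = 0.355 with an estimated correlation), among them G6pdx (0.47, SE 0.07) and Hmox1 (0.92, SE 0.17), which is also in the injury list, while Nqo1 read 0.01 (SE 0.11).

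Antigen presentation genes rose in 9 of 13 members and none fell (11 adjusted over the list alone; camera adjusted p = 0.0973 with an estimated correlation). The class I light chain gene B2m went from 201 ± 13.5 to 361 ± 12.2 CPM and H2-K1 from 307 ± 13.5 to 439 ± 43.7 CPM. Of class II genes, H2-Ab1 went from 51.9 ± 4.24 to 119 ± 29.4 CPM and Cd74 from 107 ± 11.3 to 230 ± 56.4 CPM. The single WT library of 129S2_SvPasCrl also read high, at 116 CPM for H2-Ab1 and 176 CPM for Cd74, while that of DBA_2J read 33.6 and 73.5 CPM. High class II levels were thus not limited to animals without Ehhadh. Complement and NF-κB genes rose in 5 of 13 (7 rose and 2 fell adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), among them Cxcl16 (0.87, SE 0.10) and Nfkb2 (0.55, SE 0.10). Of 19 interferon response genes, 3 rose (3 rose and 2 fell adjusted over the list alone), with Ifit2 at 0.75 (SE 0.16), and the list was not called (median −0.06, mean 0.02, camera direction upward, adjusted p = 0.8).

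Lists of immune cell markers were not called. Of 16 macrophage genes, Cd14 rose (0.78, SE 0.13) and Csf1r fell (−0.64, SE 0.08), the same adjusted over the list alone, with a median of 0.04, a mean of 0.02 and a downward camera direction (adjusted p = 0.914). No member of the T and NK cell list (12 tested), the B cell list (6) or the 3 tested neutrophil genes passed, over all genes or over the list alone. Ccl5 read a log2 fold change of 0.82 (SE 0.24; adjusted p = 0.0502 in edgeR, and 0.0283 without KO replicate 2), and Cd22 0.316 ± 0.185 CPM in KO and 0.661 ± 0.177 in WT. Cd3e passed in edgeR without WT replicate 1 (log2 fold change 2.31, adjusted p = 0.0484, against 1.42 and 0.185 with all libraries). The T and NK cell list had a camera adjusted p of 0.799 and the B cell list of 0.461. In animals with and without a leading E in their titles, list medians were 0.52 and −0.38 for T and NK cells. For macrophages they were 0.28 and −0.2, and for B cells −0.29 and −0.22.

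In the peroxisomal and mitochondrial β-oxidation lists every gene called over all genes was lower in KO, but most members did not pass and no list was called with an estimated correlation. Of 26 peroxisomal β-oxidation genes other than Ehhadh, 8 fell and none rose (14 fell and 1 rose adjusted over the list alone; median −0.22; adjusted p = 0.163 with an estimated correlation). They included the oxidase gene Acox3 (349 ± 16.9 to 282 ± 3.05 CPM), the racemase gene Amacr (292 ± 40.2 to 198 ± 24.4 CPM) and the very long chain acyl-CoA synthetase gene Slc27a2 (log2 fold change −0.32, SE 0.06). Hsd17b4, which encodes the other peroxisomal multifunctional enzyme, read −0.03 (SE 0.07) and did not pass. Other peroxisomal enzymes fell in 5 of 18 (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.072 with an estimated correlation), such as Gstk1 (−0.39, SE 0.07). Of 19 peroxin genes 2 fell, over all genes and over the list alone, Pxmp2 (−0.51, SE 0.07) and Pex6, and the list was not called (adjusted p = 0.107). The call of Pex6 was lost without KO replicates 1, 2 or 3 or WT replicates 1, 2 or 3 (adjusted p = 0.0501 to 0.0813 in edgeR). Mitochondrial β-oxidation genes fell in 3 of 20 (4 adjusted over the list alone; adjusted p = 0.573 with an estimated correlation), led by Etfb (−0.35, SE 0.07). That list's preset call was lost without KO replicate 3 (0.203), WT replicate 1 (0.147) or WT replicate 4 (0.0661).

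PPARα target genes, which respond to fatty acids, were not called as a list (median 0.01, mean 0.05, camera direction downward, adjusted p = 0.709). Of 22 members 1 rose and 2 fell (1 and 3 adjusted over the list alone). Plin2, a lipid droplet coat gene, rose (379 ± 144 to 814 ± 332 CPM), and Acaa1b was among those that fell. In edgeR the call of Plin2 was lost without KO replicates 1 or 2 or WT replicates 2, 3 or 4 (adjusted p = 0.0822 to 0.105), and that of Acaa1b without any 1 library but WT replicates 3 or 4 (0.0548 to 0.0834). Cyp4a14 read 2147 ± 1109.9 CPM in KO and 1720 ± 516 in WT and did not pass. ω-Oxidation genes fell in 1 of 14, over all genes and over the list alone, Cyp4f15, whose call was lost without KO replicate 1 or WT replicates 2 or 4 (adjusted p = 0.053 to 0.0643 in edgeR; adjusted p = 0.199 for the list with an estimated correlation; preset call lost without WT replicate 1, 0.0629, or WT replicate 4, 0.06). Cholesterol synthesis genes rose in 5 of 24 and fell in 2 (6 and 2 adjusted over the list alone), with Sqle (55.6 ± 6.42 to 89.7 ± 10.6 CPM) among the higher and Cyp51 and Ebp lower. The call of Cyp51 was lost in edgeR without KO replicate 1 (adjusted p = 0.0655), WT replicate 2 (0.0504) or WT replicate 3 (0.0689). The cholesterol list was called upward with the preset correlation, but not with an estimated one (adjusted p = 0.355) or without KO replicate 4 (0.111). Fatty acid synthesis genes went both ways, with Fads1 higher and Scd2 and Acacb lower of 18, the same over the list alone (list adjusted p = 0.617). The call of Acacb was lost without KO replicates 1 or 3 or WT replicates 1, 3 or 4 (adjusted p = 0.0502 to 0.0579 in edgeR).

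Nuclear genes of oxidative phosphorylation fell in 4 of 33 (10 adjusted over the list alone; adjusted p = 0.355 with an estimated correlation), led by Ndufs7 (242 ± 13.8 to 200 ± 6.03 CPM). The calls of Ndufb5 and Ndufs3 were lost whichever library was left out (adjusted p = 0.0555 to 0.108 and 0.055 to 0.11 in edgeR). That of Ndufs6 was lost without KO replicate 2 or WT replicates 3 or 4 (0.0576 to 0.0842). Genes of gluconeogenesis and ammonia production fell in 2 of 11 (5 adjusted over the list alone; adjusted p = 0.0973 with an estimated correlation), Pcx (−0.43, SE 0.08) and Mdh1 (−0.28, SE 0.06). In glycolysis the platelet-type phosphofructokinase gene Pfkp rose (46.8 ± 6.27 to 144 ± 23.3 CPM) and 4 of 16 genes fell, Pkm and Pdk1 among them (2 rose and 6 fell adjusted over the list alone). That list had a median of −0.13, a mean of 0.03 and a camera adjusted p of 0.461. Of 13 genes of the unfolded protein response, Dnajb9 alone rose, over all genes and over the list alone, and its call held only without KO replicate 3 or WT replicate 2 among the fits with 1 library left out (adjusted p = 0.0529 to 0.0995 in the others in edgeR). The camera adjusted p of that list was 0.0872, and 0.0266, 0.0192 and 0.00648 without KO replicate 1, KO replicate 3 and WT replicate 4.

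Markers of the collecting duct and distal tubule were lower in KO. Of 9 principal cell genes 7 fell (8 adjusted over the list alone; median −0.57). These are the salt and water transporting cells of the collecting duct, and the members included the epithelial sodium channel subunits Scnn1b (75.4 ± 4.66 to 45.5 ± 4.49 CPM) and Scnn1g (51.9 ± 3.4 to 34.9 ± 3.35 CPM). Hsd11b2, which protects the mineralocorticoid receptor from glucocorticoids, went from 187 ± 9.68 to 133 ± 8.47 CPM. Of 11 genes of the acid-base transporting intercalated cells 8 fell (9 adjusted over the list alone; median −0.52), such as the proton pump subunits Atp6v1b1 (104 ± 4.96 to 69.7 ± 5.1 CPM) and Atp6v1g3 (41.1 ± 3.6 to 25.4 ± 1.28 CPM). Distal convoluted tubule genes fell in 5 of 9 (7 adjusted over the list alone; median −0.48; adjusted p = 0.072 with an estimated correlation), Emx1, Klk1, Slc8a1 and Trpm6 among them, with Klk1 at 2114 ± 89.9 CPM in WT and 1417 ± 180 CPM in KO.

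Genes of other nephron segments and of sex-dependent lists were compared too. Thick ascending limb genes fell in 2 of 8 (3 adjusted over the list alone; median −0.21), Kcnj1 (−0.48, SE 0.10) and Slc12a1, and the preset call was lost with an estimated correlation (adjusted p = 0.355) and without KO replicate 3 (0.124). The call of Slc12a1 was lost without KO replicates 1, 2 or 3 or WT replicates 1 or 3 (adjusted p = 0.0596 to 0.0786 in edgeR). Of 11 genes of the last proximal tubule segment 3 fell (5 adjusted over the list alone; median −0.28; adjusted p = 0.0671 with an estimated correlation), with Slc7a13 going from 556 ± 122 to 275 ± 26.6 CPM. Of 17 genes of the earlier proximal segments, Slc22a8 (−0.44, SE 0.07) and 3 others fell and Slc7a7 rose (2 rose and 5 fell adjusted over the list alone), and the list was not called (adjusted p = 0.0733), though it was without KO replicate 4 (0.00406). Androgen-induced kidney genes, which overlap the last segment in Slc7a13 and Acsm3, fell in 6 of 14 (9 adjusted over the list alone; adjusted p = 0.0671 with an estimated correlation), with Cyp2e1 going from 1791 ± 279 to 975 ± 234 CPM. The call of Acsm3 was lost in edgeR without KO replicate 1 (adjusted p = 0.0748), KO replicate 4 (0.0588), WT replicate 1 (0.0826) or WT replicate 2 (0.0757). Genes higher in female kidney fell in 1 of 8, Prlr (3 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation; preset call lost without KO replicate 3, 0.0931, or WT replicate 4, 0.0786).

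None of 10 podocyte genes passed, over all genes or over the list alone (median −0.005; Nphs1 0.20, SE 0.11; Clic3 −0.39, SE 0.15; camera adjusted p = 0.999). Endothelial genes fell in 2 of 12 (5 adjusted over the list alone; median −0.27; adjusted p = 0.438 with an estimated correlation), Tie1 and Kdr. Tie1 kept its call only without KO replicate 3 or WT replicate 1 (adjusted p = 0.0533 to 0.0852 in edgeR without each other library), and Kdr only without KO replicate 3 (0.0615 to 0.0972). Of 9 stroma and mural cell genes, Myh11 (29.6 ± 2.92 to 16.1 ± 1.88 CPM) and Rgs5 fell and Cspg4 rose (1 rose and 4 fell adjusted over the list alone; adjusted p = 0.163 with an estimated correlation; preset call lost without KO replicate 4, 0.0727). Matrix genes went both ways, 2 of 22 up, Tgfb1 (11.3 ± 2.38 to 22.6 ± 2.88 CPM) and Col4a1, and 2 down, Acta2 (−0.62, SE 0.08) and Tagln, the same over the list alone (list adjusted p = 0.399). Col4a1 kept its call only without WT replicate 1 (adjusted p = 0.0507 to 0.132 in edgeR without each other library), and Tagln only without KO replicate 1 or WT replicate 4 (0.0596 to 0.117).

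Lists of tissue that could adhere to a kidney sample, and of technical groups, were not called. Adipose genes (9 tested) had a median of −0.28 (adjusted p = 0.432) and urothelial genes (7) of −0.22 (adjusted p = 0.268), with no member passing over all genes or over the list alone. These medians hide opposite signs in animals with and without a leading E in their titles. They were −0.71 and 0.59 for adipose, −0.6 and 0.08 for urothelial and −0.51 and 0.11 for red blood cell genes. Fabp4 read 62.2 ± 12.1 CPM in KO and 85.6 ± 31.9 in WT, and Foxq1 7.68 ± 0.793 and 9.77 ± 2.6. The adipose gene Lep passed in edgeR without KO replicate 3 (log2 fold change −2.79, adjusted p = 0.0141, against −1.52 and 0.183 with all libraries). Circadian clock genes had no member passing of 13 either (adjusted p = 0.709), Per1 reading 97.3 ± 8.97 and 69.0 ± 22.2 CPM. Without WT replicate 1 Per1 passed in edgeR (adjusted p = 0.0308), without KO replicate 2 Bhlhe41 did (0.0446), and without KO replicate 4 Dbp did (log2 fold change −1.11, adjusted p = 0.0419, against −0.23 with all libraries). Of 28 ribosomal protein genes Rps9 rose (none adjusted over the list alone; adjusted p = 0.268), and of 13 immediate early genes Btg2 rose (2 adjusted over the list alone; adjusted p = 0.161, but 0.00433 without KO replicate 4 and 0.0262 without WT replicate 3). Rps9 kept its call only without KO replicate 3 or WT replicate 4 (adjusted p = 0.0587 to 0.0973 in edgeR without each other library), and Btg2 only without KO replicate 4 or WT replicate 3 (0.0601 to 0.076). The red blood cell list (6 tested) held 1 lower gene, Slc4a1, which is also an intercalated cell gene, over all genes and over the list alone. Its adjusted p was 0.0678, and 0.000601 without KO replicate 2 and 0.0431 without WT replicate 4.

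**Figure D2:**
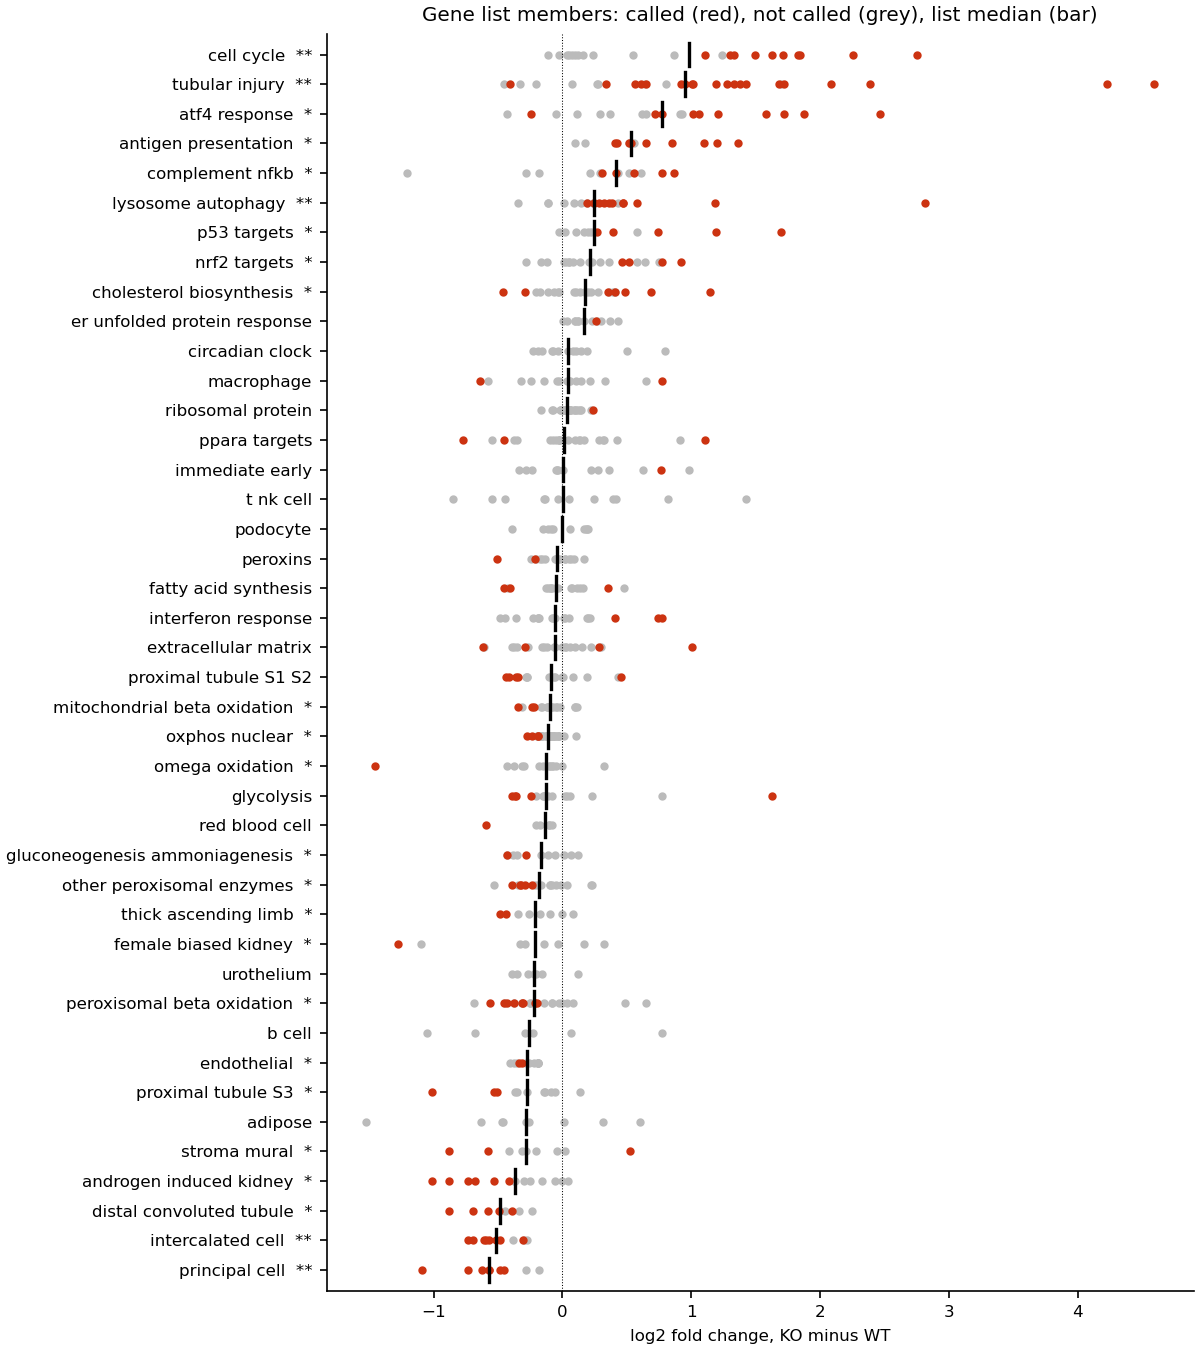
Log2 fold change (KO minus WT) of each tested member of the 42 gene lists; red dots are genes called by edgeR, grey dots are not, and black bars are list medians. Lists marked * were called by camera with the preset correlation, and those marked ** also with an estimated one; tubular injury and cell cycle lie highest, principal and intercalated cell lists lowest.

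A targeted allele can carry flanking sequence from another strain, so genes around Ehhadh were examined. The nearby gene with the smallest p was Arvcf (chromosome 16, 18348182 to 18407074), which went from 46.4 ± 2.83 CPM in WT to 103 ± 7.4 in KO (log2 fold change 1.15, SE 0.07; edgeR adjusted p = 1.36e-05). Counting ignored strand and gave a shared read to each gene, so the level of Arvcf is uncertain. Dnase1 and Myh11, named above, and Car15 (−0.64, SE 0.09) were lower, and Nr1i2, the pregnane X receptor gene, was higher (0.79, SE 0.10).

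Within 20 Mb on either side of Ehhadh, 40 of 304 tested genes were called (13.2%), against 1669 of 15242 elsewhere (11%). The odds ratio was 1.23 (95% confidence interval 0.857 to 1.73; two-sided Fisher's exact p = 0.228), so no excess of calls was shown. Leaving out KO replicate 4 gave an odds ratio of 1.46 (two-sided Fisher's exact p = 0.0291). In the 129S2_SvPasCrl library Arvcf read 91.9 CPM and in the DBA_2J library 98.8 CPM, both above the WT mean. Myh11 was lower in both (log2 differences −0.80 and −0.76). Other nearby genes differed from WT against the direction of KO in 129S2_SvPasCrl, with log2 differences of −0.49 for Nr1i2, 0.71 for Car15 and 0.67 for Dnase1, and in DBA_2J these were −1.13, 0.13 and −0.54. The plasma protein genes Fetub, Hrg, Kng2 and Kng1, of which all but Hrg were singled out after their values were seen, lie together between 22918382 and 23082078 and were lower in KO. The log2 fold changes were −1.23 for Fetub (SE 0.30), −2.22 for Hrg, −0.34 for Kng2 (SE 0.07) and −0.63 for Kng1 (SE 0.14). In edgeR Fetub lost its call without KO replicate 1 (adjusted p = 0.0651), KO replicate 2 (0.0547), KO replicate 3 (0.0586), WT replicate 3 (0.0866) or WT replicate 4 (0.0505), and Kng1 without WT replicate 3 (0.058). From Fetub to Kng1 in that order, the differences from WT were −1.94, −1.10, −0.45 and −0.60 in the 129S2_SvPasCrl library and −2.15, −1.08, −0.38 and −0.67 in the DBA_2J library. The class II transactivator gene Ciita, also within 20 Mb and chosen after its values were seen, went from 2.80 ± 0.658 to 7.24 ± 3.07 CPM in KO and read 6.76 CPM in the 129S2_SvPasCrl library and 3.35 CPM in the DBA_2J library. Its call was lost without WT replicate 1 (adjusted p = 0.0506) or WT replicate 2 (0.0507).

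**Figure D3:**
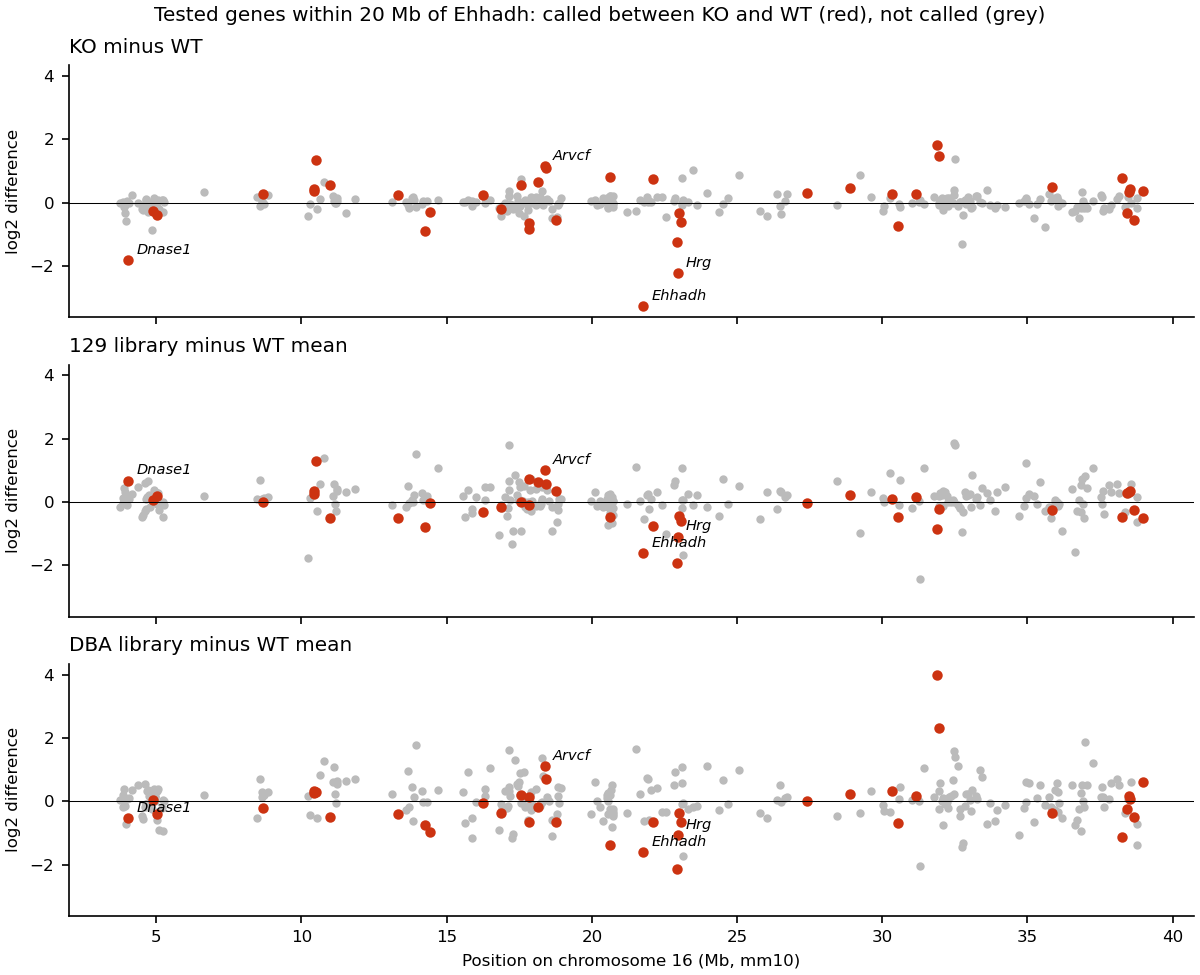
Log2 differences of tested genes within 20 Mb of Ehhadh along chromosome 16 (position in Mb, mm10), for KO minus WT and for each single strain library minus the WT mean; red dots are the genes called between KO and WT (40 besides Ehhadh). Arvcf lies above 0 and Hrg and Ehhadh below 0 in all 3 panels, while Dnase1 is lower in KO and higher in the 129S2_SvPasCrl library.

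The WT animals of the other strains were set beside WT, with 1 library each and so no replicate check and no test. PPARα target genes were far lower in both strain libraries than in WT. The labels give neither feeding state nor time of collection, so these values, and those of the clock genes below, need not be differences of strain. Cyp4a14, a fatty acid ω-hydroxylase gene, read 6.03 CPM in 129S2_SvPasCrl and 8.03 in DBA_2J against 1709 ± 513 CPM in WT (SD, n = 4). Of other members, singled out after their values were seen, Pdk4 read 15.5 and 14.4 against 358 ± 126 CPM, Plin2 25.3 and 15.9 against 376 ± 143, and Angptl4 42.5 and 14.4 against 302.5 ± 70.2. The list's median difference was −2.04 in 129S2_SvPasCrl and −2.73 in DBA_2J, percentile 0 among 10000 random lists of matched expression in each. Genes of a list can vary together (estimated correlation 0.388 for this one), unlike those of a random list. The state of 1 animal can thus bring a whole list to an extreme percentile, here and in the lists below. Peroxisomal β-oxidation (medians −0.66 and −0.51) and mitochondrial β-oxidation genes (−0.62 and −0.68) were also at percentile 0 in both.

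By the rule of a log2 difference of 2 or more, outside the WT range and with 5 CPM or more on the higher side, 58 genes were higher and 103 lower in 129S2_SvPasCrl, and 97 higher and 125 lower in DBA_2J. Of these genes 86 were listed in both libraries, 82 with the same sign. Angptl7 (433 and 453 CPM against 5.81 ± 0.99), Col6a6 (64.1 and 71.5 against 0.958 ± 0.189) and Eddm3b (12.4 and 27.1 against 0.249 ± 0.0875) were high in both. Klk1b22 (28.7 CPM), Havcr1 (62.8 against 1.80 ± 0.564 CPM) and Sox2ot (15.2 CPM) led in 129S2_SvPasCrl, and Alox15 (360 against 0.542 ± 0.223 CPM), Hdc (399 against 15.6 ± 1.63) and Pianp (8.66 CPM) in DBA_2J. Among the lowest in 129S2_SvPasCrl were Ugt2b38 (2.27 against 608 ± 65.5 CPM), Gm14403, of which 1 read was counted, Serpina1d (1.88 against 86.1 ± 7.34) and Etohi1 (0.218 against 9.19 ± 0.981). In DBA_2J, Azgp1 (0.645 CPM), Gcnt1 (2.60), Sbsn (0.0184) and Creb3l3 (0.0737) were among the lowest, as was Cyp4a14. Reads of a strain that differ from the C57BL/6 reference, and members of gene families such as Ugt2b38, Klk1b22 and Gm14403, can be counted wrongly, so these levels are uncertain.

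Other lists set the strain libraries apart from WT in both cases. Cell cycle (medians 1.10 and 0.97), cholesterol synthesis (0.37 and 0.61) and unfolded protein response genes (0.70 and 0.83) were at percentile 100 in 129S2_SvPasCrl and DBA_2J, as were androgen-induced genes (0.46 and 1.25). Genes of the last proximal tubule segment had medians of 0.57 and 1.24. Circadian clock genes had medians of 0.86 (percentile 100) and 0.54 (99.96), with Dbp at 229 and 91.6 CPM against 55.6 ± 25.3 in WT and Arntl at 1.74 and 3.65 against 10.5 ± 3.33. Red blood cell genes (−1.19 and −1.68) and adipose genes (−1.66 and −1.59) were low. Tubular injury genes had medians of −0.59 and −0.60, although Havcr1 was high in 129S2_SvPasCrl. Collecting duct genes parted the strains, with principal cell medians of −0.06 and −0.48 and intercalated cell medians of 0.12 and −0.57.

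**Figure D4:**
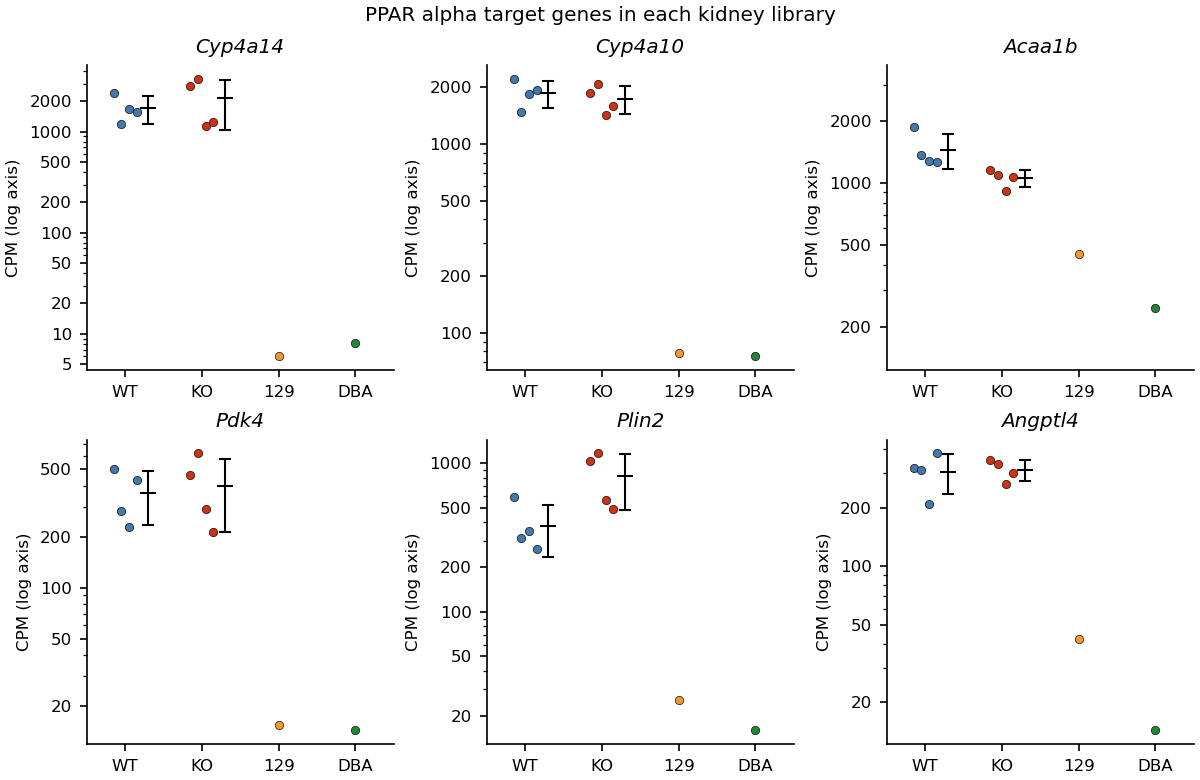
CPM (log axis) of 6 PPARα target genes in each library of WT, KO, 129S2_SvPasCrl (129) and DBA_2J (DBA); dots are animals, bars the mean ± SD of 4 animals. For all 6 genes both strain libraries lie below every WT and KO library.

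Differences of KO and of the strain libraries from WT were then compared across 15546 genes, which are not independent replicates. The covariance of the KO and 129S2_SvPasCrl differences was 0.0296 (Pearson r = 0.115), against 0.0221 (r = 0.352) for simulated unchanged groups, which share the WT libraries in the same way. For DBA_2J the covariance was 0.0574 (r = 0.195), against 0.0221 (r = 0.354). The simulated libraries hold no differences of genotype or strain and so vary less, and their r cannot be set against the measured r. With the WT libraries split into 2 and 2, so that no control was shared, the covariances were 0.005 (r = 0.018) and 0.0327 (r = 0.101), against 0.0001 in simulation. Genes within 20 Mb of Ehhadh alone gave 0.0439 and 0.1024, and all genes outside it 0.0293 and 0.0564.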

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

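The tests of podocyte, endothelial and proximal tubule markers beside those of the collecting duct were chosen only after the result was seen. Thinning was chosen after the depths were seen, but its tests, like the others below, were fixed before their own results. In 21 of 304 groups of 4 values (2 genotypes, the genes named by the fixed rule and total counts), 1 library lay far from the other 3 by Dixon's ratio of gap to range; chance gives about 5% of groups. In KO the ratio was 0.834 for Agps (KO replicate 1), 0.89 for Gm3376, 0.839 for Lep and 0.836 for Scnn1g (KO replicate 3). KO replicate 4 stood apart for Anxa3 (0.846), Atp6v1b1 (0.938), Bbc3 (0.871), Btg2 (0.974), Etfa (0.953), Nfkb2 (0.892) and Sqle (0.938). In WT, replicate 1 stood apart for Ehhadh (0.902; 3439 CPM against 2100 to 2232), Cd3e (0.843) and Gbp2 (0.933), replicate 2 for Ccnb2 (0.898) and Srd5a2 (0.869), and replicate 3 for Mki67 (0.94). WT replicate 4 stood apart for Atp6v1g3 (0.917), Pkm (0.832), Slc22a30 (0.833) and Slc7a7 (0.899).

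The 1710 genes called between KO and WT came with deeper KO libraries. Only the genotype split, 1 of the 35 splits of the 8 libraries, called as many genes, and the highest other split called 1. A share of 1 in 35 is the smallest that these splits can give. The other splits mix the genotypes, so the genotype difference adds to the spread within their groups and few calls are expected of them. The splits therefore cannot exclude chance. Thinned to 19.79 M counts each, the libraries still called 82.9% of these genes in the same direction, above the 80% set beforehand, and 5 further thinnings kept 82.7% to 84.1%, which argues against depth as the whole cause. Genotype remains as an explanation, together with anything else that differed between the KO and WT animals, such as what the title numbers mark.

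For the gene lists, 5 of the 35 splits called as many as the 24 of the genotype split with the preset correlation (highest other 30). Besides the genotype split, these hold 3 of the 4 KO libraries on the same side and keep part of the genotype difference. They thus cannot measure chance, and chance is not excluded for that count. With an estimated correlation only the genotype split, 1 of the 35, called as many as its 5 lists (highest other 2). That share is the smallest possible and the other splits mix the genotypes, so chance is not excluded here either.

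Principal cell and intercalated cell markers were lower in KO by 0.51 on the log2 scale (mean change over both lists −0.51, exact two-sided permutation p = 0.0286, the smallest possible). A larger share of RNA from proximal tubule cells would lower the markers of every other cell type alike, but podocyte markers changed by −0.01, which is 0.51 above the collecting duct change (exact two-sided permutation p = 0.0286). Of the called members of both lists, 93.3% (14) were still called lower after thinning, which argues against depth. Markers of the earlier proximal segments changed by −0.09 (exact two-sided permutation p = 0.229) and those of the last segment by −0.31 (p = 0.0286 in the same test), so neither set rose. Levels within proximal cells may have changed as well, so this does not measure their share of RNA. Of the other cell types compared here, only podocytes had markers close to unchanged. The change of the last segment was not told apart from the collecting duct change (difference 0.21, exact two-sided permutation p = 0.0571). Distal convoluted tubule markers changed by −0.51 too, thick ascending limb markers by −0.22 and stroma and mural cell markers by −0.24. Endothelial markers changed by −0.29, not told apart from the collecting duct change (difference 0.23, exact two-sided permutation p = 0.2). A change in the number or the expression of these cells in KO may account for the pattern, which bulk RNA does not separate, and a rise within podocytes stays open.

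Called genes near Ehhadh may reflect flanking sequence from a 129-type strain around the targeted allele. Of the 40 called genes within 20 Mb, 55% (22) differed in the 129S2_SvPasCrl library in the same direction as in KO, against 53.9% (900 of 1669) elsewhere (one-sided Fisher's exact p = 0.512), so an excess near Ehhadh was not shown. The explanation cannot be told apart from an effect of genotype for these genes, since 1 library and 40 genes decide little. Arvcf and the Fetub to Kng1 group moved as in KO in both strain libraries. Their values do not argue against flanking sequence of a 129-type strain, but they would not single out that strain either.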

How the results depend on the processing

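Thinning and the windows for agreement near Ehhadh were chosen after seeing the data. Counts of called genes stayed within 1.5 times of 982 and 728 with the title form as a term (1155 and 880), RLE, no filter, all 10 libraries, thinning, DESeq2 (1301 and 1087), limma-voom and limma on the deposited log2 values (706 and 514), and no call turned direction. An adjusted p under 0.01 gave 389 and 216, and a log2 fold change of 1 or more gave 187 and 55, both stricter by construction. Leading-E animals alone gave 92 and 51; the cause was not tested. Leaving out 1 library gave 610 to 916 higher and 381 to 722 lower genes. Ehhadh stayed lower and called with each library left out (log2 fold change −3.40 to −3.06).

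With an estimated correlation 5 of 24 lists were called. Fry called 22 of the 42 lists with a direction and 34 in either direction, but it does not compare a list with other genes. Of the lists called with the preset correlation, it left out mitochondrial β-oxidation (fry adjusted p = 0.165), NRF2 targets (0.0505) and endothelial genes (0.102). The odds ratio near Ehhadh ran from 1.25 to 1.46 with 1 library left out, and was past the threshold only at the upper value. Of 134 called genes named by the fixed rule, 96 kept the call in every fit with 1 library left out and 38 lost it in at least 1.

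For the strain libraries a difference of 1 or more gave 1624 listings, a gene in both libraries counting for each (129S2_SvPasCrl 301 higher, 356 lower; DBA_2J 456 and 511), and no minimum CPM 838 listings (100, 265, 149 and 324). The covariance with 129S2_SvPasCrl was 0.0439, 0.0618, 0.0819 and 0.1273 for genes within 20, 10, 5 and 2 Mb and 0.005 with WT split 2 and 2; with DBA_2J it was 0.1024, 0.0821, 0.1029, 0.109 and 0.0327. Small changes can be missed: 54.9% of simulated 1.5-fold changes were recovered.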

Other observations

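The Y-linked Rbmy family was the only group of Y genes with large KO changes. Of 14 tested Y genes, 9 were entries of this family, with log2 fold changes from 2.95 to 4.43, all called by edgeR. The 4 KO libraries read Rbmy at 2.37, 1.86, 3.69 and 2.06 CPM and the WT libraries at 0.154, 0.0637, 0.111 and 0.572 CPM. The DBA_2J library read 1.51 CPM and the 129S2_SvPasCrl library 0.0198 CPM. Ddx3y, Kdm5d and Eif2s3y, single-copy genes of the same chromosome, did not pass the test, and Uty was called higher, a call kept only without KO replicate 1 among the fits with 1 library left out (adjusted p = 0.0566 to 0.104 in edgeR in the others). Adjusted over the list of sex-linked genes alone, 3 of 5 were higher, Uty, Eif2s3y and Xist. The origin of the Y chromosome in the KO and WT lines is not in the labels, so the Rbmy values need not reflect the loss of Ehhadh.

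The covariance of KO and strain differences was higher for genes within 20 Mb of Ehhadh (0.0439 for 129S2_SvPasCrl and 0.1024 for DBA_2J) than for the rest (0.0293 and 0.0564). Both differences share the WT libraries, and simulated unchanged groups gave 0.0189 in the window for either library (largest of 100 simulations 0.0341 and 0.0473) and 0.0222 for the rest. Of 63 tiles of 40 Mb on other chromosomes, each with 100 or more tested genes, 18 had a covariance as high with 129S2_SvPasCrl and 7 with DBA_2J (medians 0.026 and 0.0408). Within 2 Mb the covariance was 0.1273 and 0.109 (largest simulated 0.0712 and 0.0701), and of 368 tiles of 4 Mb with 15 or more tested genes 31 and 59 were as high. With 129S2_SvPasCrl it rose as the window narrowed (0.0618 within 10 Mb, 0.0819 within 5 Mb), and 21 of 115 tiles of 20 Mb and 23 of 166 tiles of 10 Mb were as high. Other regions thus reached such values at every width, and whether flanking sequence adds to those near Ehhadh stays open. These comparisons were chosen after the values were seen.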
